A study of Mus musculus with 4 samples.

How the data were processed

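The deposited matrices held raw UMI counts per gene or antibody tag and barcode, made by Cell Ranger, per the file headers, with version 4.0.6 and genome build mm10 given in the submitters' processing notes. The file header names Cell Ranger 4 without further digits. The notes also name Seurat and DESeq without versions or steps, and neither was used on these values before deposit as far as the files show, since all values were whole numbers and no barcode had been filtered. Each matrix listed 32285 genes and 6 antibodies (CD150, CD48, CD34, CD201, CD117 and Sca1) over 2395014 barcodes in WT and 2456731 in KO. A separate list of antibody barcodes was not used, because the matrices name the antibodies. Gene names came with the matrices; 38 symbols stood for more than 1 gene identifier (78 identifiers). Gene positions came from an annotation of GRCm38.p6, the assembly of mm10.

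The 4 samples in 4 groups were the RNA and antibody parts of 1 library per genotype, each from 10 pooled embryos, with 20000 cells sorted and 10000 loaded, per the labels. With 1 library per genotype no test, standard error or count of changed genes was made. The cell filters, clustering settings, gene lists, marker lists, rule for named genes and most alternatives were chosen before the data were examined.

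Barcodes were called cells at gene UMIs of at least the larger of 1000 and 10% of the 99th percentile of the top 6000 barcodes, which came to 8178 UMIs in WT and 9992 in KO, with at least 500 genes and at most 10% mitochondrial UMIs. This left 5345 WT barcodes and 2676 KO barcodes, and 90.9% and 88.4% of gene UMIs lay in the final cells. Scrublet, run per library with an expected doublet rate of 6%, marked 0 WT and 8 KO barcodes (0.299%). At under 0.5% of cells it did not work as a caller, so doublets largely remained. Leaving out the 229 WT and 57 KO cells with the highest Scrublet scores (0.8% per 1000 cells) was added as an alternative. At a minimum of 500 UMIs 5633 WT and 3134 KO barcodes passed, and at a mitochondrial limit of 5% 4657 and 2183 cells. Empty droplets with 100 to 300 UMIs had medians of 130 gene UMIs in WT and 198 in KO, which is 0.572% and 0.580% of a median cell. Haemoglobin UMIs in lymphoid-like cells gave shares of 39.8% and 24.0% for free RNA, taken as upper bounds because the estimate counts any haemoglobin transcripts of the cells themselves as free RNA.

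UMIs were summed over cells per library and class and given as counts per 1000000 gene UMIs (CPM). Ratios carry the exact conditional binomial 95% interval of 2 Poisson counts, shares carry exact Clopper-Pearson intervals, and differences of shares carry Newcombe intervals. Intervals of list medians came from 500 Poisson resamples. All of these cover counting error only. At this depth 141419013 WT and 103500376 KO gene UMIs stood behind the levels over all cells, and 10679533 and 5401001 behind those in HSC-like cells.

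The named genes were Bclaf1; the 12 highest and 12 lowest genes over all LSK cells, and the 8 highest and 8 lowest in HSC-like cells and in the largest other class, ranked by the interval bound nearest to 0 among genes with at least 20 CPM in either library; and up to 3 members of each list. A few genes that meet this rule are not reported. Haemoglobin and sex-linked genes were kept out of the ranking. The 28 fixed lists covered interferon response, MHC class I, MHC class II, NF-kB and TNF response, immediate early genes, p53 targets, unfolded protein response, ATF4 and integrated stress response, heat shock proteins, NRF2 and oxidative stress, DNA repair, the BCL2 family, splicing factors, S phase, G2 and M phase, ribosomal proteins, ribosome biogenesis, MYC targets, mitochondrially encoded genes, nuclear oxidative phosphorylation, glycolysis, cholesterol synthesis, proteasome, autophagy and lysosome, the fetal stem cell program, quiescence, haemoglobins and sex-linked genes. A list of replication-dependent histone genes was added after the data were seen. A list's median was taken over members with at least 5 CPM on average, and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test. The 14 marker lists were those of HSCs, lymphoid, granulocyte-monocyte, megakaryocyte and erythroid progenitors, mast cells or basophils, eosinophils, B cells, T, NK or innate lymphoid cells, neutrophils, monocytes, macrophages or dendritic cells, hepatoblasts or hepatocytes, endothelial cells, and stellate or mesenchymal cells.

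Cells of both libraries were clustered together by Leiden clustering at resolution 1.0 on log counts with 2000 variable genes, 30 components and 15 neighbours, without batch integration. Bclaf1, genes differing over 2-fold between libraries (56) and haemoglobin, sex-linked, mitochondrial, ribosomal protein, immediate early, interferon and cell cycle genes were left out of the variable genes. The rule for names was set after the clusters were seen: a mean log2 fold of at least 1 over the markers, at least 3 markers detected in at least 10% of cells, at least 2 markers among the top 10 genes, and no other class with as many. Clusters that lean to a class but missed this rule stayed unnamed. Levels were compared within classes of at least 100 cells per library and clusters of at least 40. Phases were called with scanpy after thinning each cell to 13589 UMIs, the 10th percentile. CD135 was not among the antibodies, so the planned subsets that need it could not be formed, and cells were split by CD150 and CD48 with thresholds from mixtures of the centred log ratio. Gene levels within the CD150-positive, CD48-negative gate are not given, because its make-up differed between libraries.

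Alternatives changed the UMI minimum, the mitochondrial limit, doublet handling, scaling, depth per cell, background subtraction, library make-up, the low level filter, the clustering, the thinning depth and the antibody scale. Make-up was held at the WT weights of clusters, not of classes, since 58.8% of WT cells had no class name. The interval and list steps were checked on simulated counts for all LSK cells, drawn from the Poisson model that the intervals assume. This checks the calculation only, since spread between cells and linked changes within a list were not simulated. Of the intervals, 95.0% held the true ratio over 9220 genes, and 100% of 100 genes changed 2-fold and of 100 genes changed 1.25-fold had the right sign with an interval without 0. Of 100 unchanged lists of 20 genes, 4% lay outside the middle 95%, and a list raised 1.25-fold lay at percentile 100. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 (with its Scrublet), anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.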

Results

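CITE-seq, which reads messenger RNA and antibody-linked barcodes from the same single cells, was performed on LSK cells of the mouse fetal liver at E17.5 (days of gestation). LSK cells lack lineage markers and carry Sca1 and c-Kit. This gate holds haematopoietic stem cells (HSCs) and early multipotent progenitors. The control library (WT) came from embryos with floxed Bclaf1 alleles alone, and the knockout library (KO) from embryos that also carried Vav-Cre, a recombinase active in blood cells. The study's title places the question in stress responses and expansion of HSCs that lack BCLAF1, a nuclear protein linked to transcription and splicing. Each genotype was 1 pool of 10 embryos, sorted and captured as 1 library with an RNA part and an antibody part, which gave 4 samples in 4 groups. The WT library held 5345 cells with 141419013 gene UMIs (unique molecular identifiers), a median of 22734 UMIs and 4403 genes per cell. The KO library held 2668 cells with 103500376 gene UMIs, a median of 34140 UMIs and 5424 genes per cell. Median antibody UMIs per cell were 3776 in WT and 6154.5 in KO. No replicates were sequenced, so the differences have no replicate check, no test was made, and all comparisons are between these libraries, not between conditions. Brackets give 95% intervals that cover counting error only, and ratios are KO over WT. Presence of Cre and loss of Bclaf1 were not separated by this design.

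Bclaf1 itself, on chromosome 10 from 20310512 to 20342644 (mm10), was lower in the KO library. Its level was 217.8 UMIs per 1000000 gene UMIs (CPM) in WT and 75.9 CPM in KO, a log2 ratio of -1.52 (-1.56 to -1.49), so the KO library kept 34.8% of the WT level. The ratio was -1.19 in HSC-like cells, -1.32 in lymphoid-like, -1.49 in granulocyte-monocyte-like, -1.67 in megakaryocyte-like and -1.68 in erythroid-like cells. In empty droplets with 100 to 300 UMIs the ratio was -1.16. The labels do not say which part of the gene was deleted, and the 3' tags counted here check nothing about a deletion that lies outside the tagged part.

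Over all LSK cells, Fos ranked highest in the KO library relative to WT, followed by Elane, and other immediate early and heat shock genes were among the 12 highest. Fos, a subunit of the AP-1 transcription factor, had 36.9 CPM in WT and 134.5 CPM in KO, a log2 ratio of 1.86 (1.82 to 1.91). Klf2, a transcription factor of the Krüppel-like family, had a ratio of 1.52 (1.41 to 1.62). Dusp1, a phosphatase that inactivates MAP kinases, had 1.47 (1.39 to 1.55), and Zfp36, which promotes decay of AU-rich messenger RNAs, had 1.32 (1.27 to 1.38). The inducible HSP70 genes Hspa1a and Hspa1b, which are near-identical copies and share reads, had 1.39 (1.36 to 1.42) and, from 116.8 CPM in WT and 277.5 CPM in KO, a ratio between 1.22 and 1.28. Commd10 followed at 1.31 (1.22 to 1.40) and the chemokine gene Ccl3 at 1.31 (1.21 to 1.42). For Commd10, which was higher in each of 16 clusters, presence of Cre was not told apart from loss of Bclaf1. Elane, the neutrophil elastase gene, had 1.74 (1.66 to 1.82), with 11.1% of its WT UMIs in 1 cell. Col5a1, Ermap and the metallothionein gene Mt1 had 1.24, 1.18 and 1.10 over all cells. They had 0.19, 0.096 and 0.082 within erythroid-like cells and 2.00, 2.42 and 1.45 within granulocyte-monocyte-like cells. Within HSC-like cells they had -0.82, 1.57 and 1.58, and within megakaryocyte-like cells 0.73, 1.49 and 0.021. All of these genes were among the top 10 genes of the erythroid-like cluster, which held 4.57% of WT and 11.2% of KO cells. Their ratios over all cells thus cannot be told apart from a shift in make-up. Whether free RNA or single cells gave the values in the other classes was not tested.

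Besides Bclaf1, the interferon-induced gene Isg15 and the lymphotoxin beta gene Ltb were lowest in the KO library relative to WT. Isg15 had 31.8 CPM in WT and 16.4 CPM in KO, a log2 ratio of -0.95 (-1.04 to -0.87). Ltb had -0.76 (-0.82 to -0.71), Zfp467 -0.73 (-0.81 to -0.65) and Tnfaip8l2 -0.69 (-0.76 to -0.61). Shisa8 had -0.65 (-0.72 to -0.57). Rpl36a-ps1, which shares reads with its parent gene, had -0.62, the actin-capping protein gene Capg -0.61, Eva1b -0.60, Gm1673 -0.57 and the interleukin 21 receptor gene Il21r -0.56. Several of these ratios were farther from 0 in erythroid-like than in HSC-like cells, at -1.60 and -0.030 for Isg15, -1.39 and -0.26 for Ltb, and -1.49 and -0.12 for Il21r, and these differences between classes were not tested. In erythroid-like cells Isg15 had only 5.66 CPM in WT and 1.87 CPM in KO. The upper bound on free RNA was 39.8% in WT and 24.0% in KO, so a difference in free RNA was not told apart there. Across the 9230 genes measured over all LSK cells the median log2 ratio was 0.067, and 90.1% lay between 20% lower and 25% higher.

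Among the gene lists, immediate early genes had the highest median in the KO library relative to WT, and several stress-related lists lay above most random lists. Of 16 measured immediate early genes, 15 were at least 25% higher and none was lower. Their median log2 ratio was 0.95 (0.90 to 0.97), above all 10000 random lists of matched expression (percentile 100), and Nr4a1, an orphan nuclear receptor gene, was highest at 2.03 (1.88 to 2.19). The list of ATF4 and integrated stress response genes had a median of 0.29 (percentile 100), with 12 of 13 members higher, among them Ppp1r15a, a phosphatase subunit acting on eIF2α, at 0.88, the asparagine synthetase gene Asns at 0.87 (-0.63 to 0.58 within the 5 classes) and Psat1 at 0.42. NF-kB and TNF response genes had a median of 0.22 (percentile 99.4), with Nfkbiz at 1.16 and Ier3 at 0.96. Their median was 0.20 (percentile 90.1) in HSC-like and 0.068 (percentile 56.9) in erythroid-like cells, and higher in the other classes given below. Heat shock protein genes had a median of 0.17 (percentile 99.7), and 4 of 13 were at least 25% higher, among them the co-chaperone gene Dnajb1 at 0.52. With cells thinned to the same UMIs, the heat shock median was 0.11. The quiescence list had a median of 0.17 (percentile 97.2), led by Egr1 at 0.96, Btg2 at 0.71 and Btg1 at 0.62. Egr1 and Btg2 are also members of the immediate early list.

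Medians of the other stress and survival lists lay nearer to the random lists. Unfolded protein response genes had a median log2 ratio of 0.13 (percentile 95.9), with the chaperone gene Hspa5 at 0.22 and its partner Dnajb9 at 0.61, and Edem1 at 0.31. Targets of p53 had a median of 0.13 (percentile 90.7), and 4 of 16 were at least 25% higher, among them Plk2 at 1.54 and the cell cycle inhibitor gene Cdkn1a at 1.26. Btg2, at 0.71, is on this list as well as on the immediate early list. In erythroid-like cells the p53 list had -0.031 (percentile 7), with 8 of 13 members lower, Cdkn1a at -0.51 and Plk2 at 0.61. NRF2 and oxidative stress genes had a median of -0.028 (percentile 14.7), or 0.015 after subtraction of the 10 to 100 UMI background, while Gclm, a subunit of the enzyme that starts glutathione synthesis, had 0.60 (0.056 to 0.28 within the 5 classes), Sod1 0.43 and G6pdx 0.34. The sign of G6pdx turned with that subtraction. DNA repair genes had 0.11 (percentile 80.6), with Fancd2 at 0.46, Bard1 at 0.31 and Brca2 at 0.26. BCL2 family genes had 0.054 (percentile 37.5), or -0.014 with median-of-ratios scaling, with the pro-apoptotic gene Bcl2l11 at 0.74, Bcl2 at 0.32 and Bok at -0.37. Within the 5 classes Bcl2l11 ran from -0.26 to 1.03 and Bok from -1.27 to 0.47. Autophagy and lysosome genes had 0.053 (percentile 38.6), or -0.016 with that scaling, with Atg12 at 0.31, Lamp2 at 0.23 and Becn1 at 0.18.

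Interferon response and MHC class I genes were lower in the KO library. Of 29 interferon response genes, 25 were lower and 10 were at least 20% lower, with a median log2 ratio of -0.20 (-0.27 to -0.19) below all random lists (percentile 0). After Isg15, Rtp4 had -0.59 and the immunoproteasome gene Psmb8 -0.46. All 7 MHC class I genes were lower, with a median of -0.15 (percentile 0.27), and H2-K1 and H2-D1, which encode classical class I heavy chains, had -0.30 and -0.28, and H2-T23 had -0.23. MHC class II genes had a median of -0.00091 (percentile 17.3), with H2-DMa at -0.35, H2-DMb1 at -0.45 and H2-Eb1 at 0.28. When both libraries were given the WT cluster weights, the interferon median was -0.071 and the MHC class I median -0.037.

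Lists of RNA processing and growth genes moved in different directions. Of 35 splicing factor genes, 31 were higher in the KO library, with a median log2 ratio of 0.15 (percentile 100). The largest ratios were those of the SR protein gene Srsf5 at 0.49 (0.47 to 0.52), of Thrap3, which encodes a protein related to BCLAF1, at 0.49 (0.46 to 0.52), and of Clk1, a kinase of SR proteins, at 0.48 (0.45 to 0.52). All 24 ribosome biogenesis genes were higher, with a median of 0.14 (percentile 99.5) Nolc1 at 0.28, Mybbp1a at 0.27 and Ddx21 at 0.25. Of 81 ribosomal protein genes, 65 were lower, with a median of -0.086 (percentile 0.02), Rps18 at -0.19, Rpl13 at -0.18 and Rpl23a at 0.19. The median of MYC targets was 0.062 (percentile 89.9), which was -0.0070 with median-of-ratios scaling, and Myc itself had 0.27, Odc1 0.27 and Ncl 0.23. The proteasome list had -0.019 (percentile 5.57), where the immunoproteasome gene Psmb9 had -0.40 and the regulatory subunit gene Psmd1 0.29.

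All 52 measured genes of G2 and M phase were higher in the KO library, 17 of them by at least 25%, with a median log2 ratio of 0.27 (percentile 100). The centromere protein gene Cenpf had 0.51, the mitotic kinesin gene Kif11 0.51 and Hmmr 0.50. With the WT cluster weights this median was 0.18. The 42 S phase genes had a median of 0.099 (percentile 89.7), with Dtl at 0.35, E2f8 at 0.33 and the uracil-DNA glycosylase gene Ung at -0.38. Ung was a top gene of cluster 2, which held 16.0% of WT and 9.03% of KO cells, so make-up was not told apart for it.

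Mitochondrially encoded genes had a median log2 ratio of 0.098 (percentile 97.8), with mt-Nd1 at 0.26, mt-Nd6 at 0.23 and mt-Nd3 at 0.20. Nuclear genes of oxidative phosphorylation had -0.021 (percentile 16.4), with Ndufa13 at -0.27 Cox6b2 at 0.36 (-0.036 to 0.23 within the 5 classes) and Cox6a1 at 0.20. Glycolysis genes had 0.12 (percentile 94.9), with the monocarboxylate transporter gene Slc16a3 at 0.77 and hexokinase 1 (Hk1) at 0.55 (0.17 to 0.36 within the 5 classes) and Pfkp at 0.37. Cholesterol synthesis genes had -0.032 (percentile 1.51), with Fdps at -0.25 and Msmo1 at -0.26. The fetal stem cell program had -0.020 (percentile 9.98), with Mycn at -0.49, Lin28b at 0.21 and Igf2bp3 at 0.15. Of 3 measured haemoglobin genes, Hba-a1 and Hba-a2 had 0.84 and 0.90 and Hbb-bt -0.48; the list median of 0.84 was -0.11 with the WT cluster weights. The 6 sex-linked genes had a median of 0.24 (percentile 98.3), with both Tsix, transcribed from the X chromosome, at 0.29 and the Y-linked genes Uty at 0.38 and Ddx3y at 0.26, and each pool held embryos of unstated sex.

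Clusters were named from markers fixed beforehand, and the KO library held a smaller share of HSC-like cells and a larger share of erythroid-like cells. The HSC-like share was 13.0% (12.1 to 13.9) of WT cells and 9.71% (8.61 to 10.9) of KO cells, a difference of -3.26 points (-4.67 to -1.79). Erythroid-like cells made up 4.57% (4.02 to 5.16) and 11.2% (10.1 to 12.5), a difference of 6.68 points (5.39 to 8.04). Lymphoid-like cells made up 8.83% and 6.90% (-1.93 points, -3.13 to -0.68). Granulocyte-monocyte-like cells made up 7.69% and 9.78% (2.09 points, 0.79 to 3.46). Megakaryocyte-like cells made up 5.05% and 7.72% (2.67 points, 1.53 to 3.88). Mast cell-like cells made up 1.33% and 1.69%, and monocyte or dendritic-like cells 0.748% and 0.750%. Clusters without a name held 58.8% and 52.2% of cells. Of these, cluster 2 held 16.0% and 9.03%. The HSC-leaning clusters 11 and 12 held 3.57% and 2.59%, and 7.80% and 7.16%. Cluster 14, with granulocyte-monocyte and basophil genes, held 1.59% and 3.52%, and the erythroid-leaning cluster 17 held 0.0935% and 0.937% (5 and 25 cells). Median mitochondrial shares in cluster 17 were 0.600% and 0.828%, against 3.81% and 4.10% in erythroid-like cells, and its top genes were Gm26917 and Gm42418. Its larger share in KO is therefore not read as more erythroid cells.

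Shares are those of cells sorted for Sca1 and c-Kit and called at a UMI minimum of 8178 in WT and 9992 in KO. With KO cells weighted to the WT spread of Sca1 tag shares, a check chosen after the data were seen, the HSC-like difference was 1.16 points (-0.013 to 2.49), the granulocyte-monocyte-like difference 0.39 points (-0.52 to 1.38), the megakaryocyte-like difference 1.02 points (0.26 to 1.89) and the erythroid-like difference 5.76 points (4.66 to 6.82). Among cells with at least 2 times the UMI minimum the HSC-like difference was 0.29 points (-0.90 to 1.56), and HSC-like cells had median depths of 14486 UMIs in WT and 20075 UMIs in KO. With clusters from WT cells alone the granulocyte-monocyte-like difference was 0.37 points and the megakaryocyte-like difference 1.06 points, and with genes that differed over 2-fold kept in the clustering the lymphoid-like difference was -0.067 points.

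**Figure D1:**
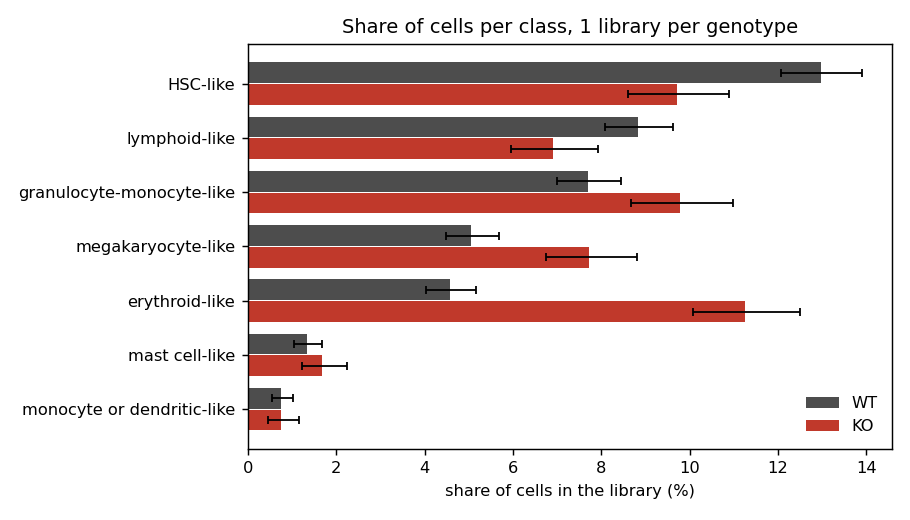
Share of cells (%) in each named class in the WT and KO libraries, with 1 library per genotype and exact 95% binomial intervals as error bars. HSC-like cells make up 13.0% of WT and 9.71% of KO cells, and erythroid-like cells 4.57% and 11.2%.

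Within HSC-like cells (693 in WT, 259 in KO), early response transcription factor genes were highest in the KO library relative to WT. Fos had 43.6 CPM in WT and 219.2 CPM in KO, a log2 ratio of 2.33 (2.17 to 2.49). The orphan nuclear receptor genes Nr4a2 and Nr4a1 had 2.54 (2.10 to 3.01) and 1.95 (1.54 to 2.38), and Klf2 had 2.29 (2.01 to 2.58). The polo-like kinase gene Plk2 had 1.79, Hspa1a 1.56, Zfp36 1.54, and Hist1h2ap, a histone H2A gene that shares reads with other copies, 1.41 (1.37 to 1.45). The lowest after Bclaf1 was Bc1, a neuronal small RNA, at -0.77 (-1.12 to -0.44), followed by Slc6a13 at -0.76, Gtpbp8 at -0.75, Rpl36a-ps1 at -0.69, Tmem238 at -0.68, Gm3448 at -0.66 and AY036118 at -0.41. HSC marker genes that differed over all LSK cells stood closer to 0 within this class, at -0.39 and 0.11 for Mecom, -0.54 and -0.040 for Procr, and -0.41 and 0.14 for Ly6a, markers picked after their values were seen. The class was named by a marker list that holds these genes, so such small ratios may follow from how the class was formed.

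Immediate early genes had a median log2 ratio of 0.99 (0.92 to 1.07, percentile 100) in HSC-like cells, and ATF4 and integrated stress response genes 0.34 (percentile 99.96), led by Cebpb at 0.56 and Ppp1r15a at 0.54. Targets of p53 had 0.29 (percentile 99.7), with Cdkn1a at 1.43, quiescence genes 0.27 (percentile 99.6), with the thioredoxin inhibitor gene Txnip at 0.42, and splicing factors 0.12 (percentile 99.8). The p53 and quiescence lists share Btg2 with the immediate early list, and the quiescence list also shares Egr1, so these medians are not independent. Genes of the fetal program had 0.25 (percentile 99.1), with H19 at 0.47, where 11.9% of KO UMIs lay in 1 cell, Igf2bp2 at 0.33 and Hmga2 at 0.25. Heat shock genes had 0.038 (percentile 64.1), which was -0.067 with median-of-ratios scaling, although Hspa1b had 0.78 and Dnajb1 0.44. Lower medians were those of nuclear oxidative phosphorylation genes at -0.13 (percentile 0, 67 of 75 lower, Atp5g1 at -0.28), the proteasome at -0.084 (percentile 0.03, Psmb10 at -0.35) and ribosomal proteins at -0.098 (percentile 0.045). Interferon response genes had 0.11 (percentile 70.6), with Psmb8 at -0.35, Bst2 at -0.34 and Ifit1 at 1.21, where 1 cell held 29.0% of the KO UMIs. Myc had 0.68 and Mcl1, an anti-apoptotic gene, 0.37.

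Further list members taken by the rule for named genes within HSC-like cells follow, and the intervals of Cd74, Brca1 and Sqstm1 held 0. The G2 and M phase list had a median log2 ratio of 0.15 (percentile 88.5, 25 of 32 higher), with the proliferation marker gene Mki67 at 1.05 (7.68 CPM in WT, 15.9 CPM in KO), Psrc1 at 0.88 and the centromeric histone gene Cenpa at 0.62. Of S phase genes, Atad2 had 0.35 and Pcna 0.20. The DNA repair genes Brca2 and Brca1 had 0.45 and 0.20, Bcl2l1 had 0.43, and the peptide transporter gene Tap1 had -0.65 and Cd74 0.11. Stress genes were Sel1l at 0.37, Slc3a2 at 0.46, Taldo1 at -0.35 and Fth1 at -0.18. Ribosome genes were Rpl8 at -0.23, Rpl13 at -0.19, Ddx21 at 0.26, Utp20 at 0.41 and Ncl at 0.11, with Odc1 at 0.38 and Nme2 at -0.20. Mitochondrial genes were mt-Atp8 at -0.33, mt-Nd6 at 0.35, mt-Nd3 at 0.24 and Atp5d at -0.23. Metabolic and degradation genes were Hk2 at 0.51, Slc2a3 at 0.47, Ldha at -0.18, Pmvk at -0.31, Psmb6 at -0.28, Atg7 at 0.47 and Sqstm1 at 0.15. Hbb-bs had 1.33, Xist 0.38, Ddx3y 0.42, and the histone genes Hist1h2br and Hist1h2bc 1.18 and 0.97.

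**Figure D2:**
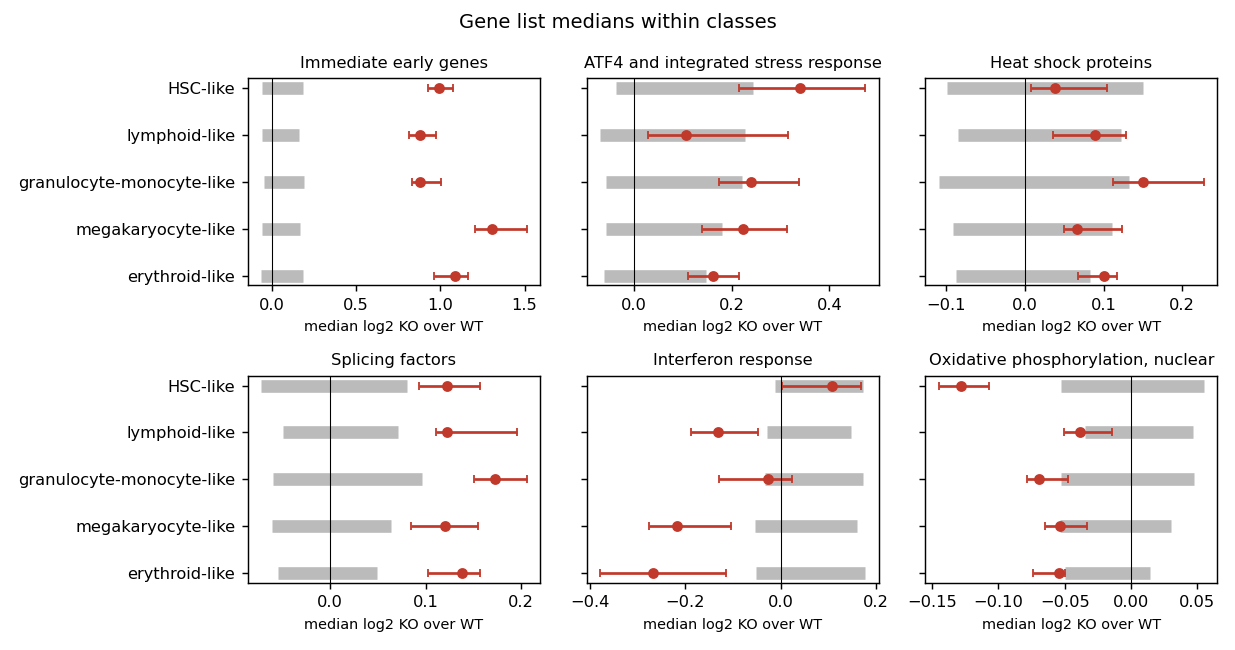
Median log2 ratio (KO over WT) of 6 gene lists in 5 classes, as points with 95% counting intervals, over grey bars that hold the middle 95% of 10000 random lists. Immediate early genes lie above the grey bars in each class, from 0.88 to 1.31, and interferon response medians run from -0.27 in erythroid-like to 0.11 in HSC-like cells.

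In granulocyte-monocyte-like cells (411 in WT, 261 in KO), the largest other class, chemokine and immediate early genes were highest in the KO library relative to WT. Ccl4 had a log2 ratio of 2.25 (2.05 to 2.47), Ccl3 1.99 (1.80 to 2.19), Dusp1 2.07 (1.74 to 2.41), Fos 1.68 (1.58 to 1.78), Ier3 1.70 (1.51 to 1.89), Cdkn1a 1.70 (1.41 to 2.00) and Elane 1.51 (1.43 to 1.59). The metallothionein gene Mt2 had 2.39, with 45.2% of its KO UMIs in 1 cell. Of the lowest genes, 3 rested on single cells. Ngp, a neutrophil granule gene, had 550 UMIs in WT, 98.7% of them in 1 cell, and 0 UMIs in KO. Camp had -2.00 and Cstdc4 -1.54, with 78.6% and 71.1% of their WT UMIs in 1 cell. Klrd1 had -1.27 (-1.57 to -0.98), the creatine kinase gene Ckb -1.23, Ptms -0.89 and Shisa8 -0.89. Immediate early genes had a median of 0.88 (percentile 100), NF-kB and TNF response genes 0.40 (percentile 99.98), and all 21 unfolded protein response genes were higher, with a median of 0.30 (percentile 100).

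In lymphoid-like cells, immediate early genes had a median log2 ratio of 0.88, NF-kB and TNF response genes 0.56, quiescence genes 0.46 and G2 and M phase genes 0.46, each at percentile 100. Megakaryocyte-like cells lay mostly in cluster 16 in WT (152 of 270) and in cluster 8 in KO (105 of 206). There, immediate early genes had 1.31 and NF-kB and TNF response genes 0.74, both at percentile 100, and all 7 MHC class I genes were lower, with a median of -0.21 (percentile 0.025). The MHC class I median was -0.12 in erythroid-like, -0.038 in HSC-like, -0.028 in lymphoid-like and 0.031 in granulocyte-monocyte-like cells. Erythroid-like cells had a median of 1.09 for immediate early genes (percentile 100), -0.27 for interferon response genes (percentile 0) and -0.43 for haemoglobins (percentile 0), all 4 of which were lower. Haemoglobins made up 0.0222% of UMIs in WT and 0.0172% in KO in erythroid-like cells, near the 0.0192% and 0.0136% in lymphoid-like cells (median -0.50). The latter were used to bound free RNA, so a difference in free RNA was not told apart here. Cd34, looked at after its value was seen, had in erythroid-like cells 20.4 CPM in WT and 7.13 CPM in KO, a log2 ratio of -1.52 (-1.81 to -1.23). Over all LSK cells it had 194.1 and 169.8 CPM. A difference in free RNA was not told apart for Cd34 or the interferon response genes in erythroid-like cells either.

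Across the 16 clusters with at least 40 cells per library, named or not, the immediate early median ran from 0.75 to 1.60. Bclaf1 ran from -1.76 to -1.19, Fos from 1.52 to 2.39, Thrap3 from 0.32 to 0.62 and Srsf5 from 0.37 to 0.82. Hspa1a ran from -1.68 to 2.55 and Isg15 from -1.78 to -0.012. The interferon median was above 0 in 1 of the 16 clusters, the HSC-like cluster.

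**Figure D3:**
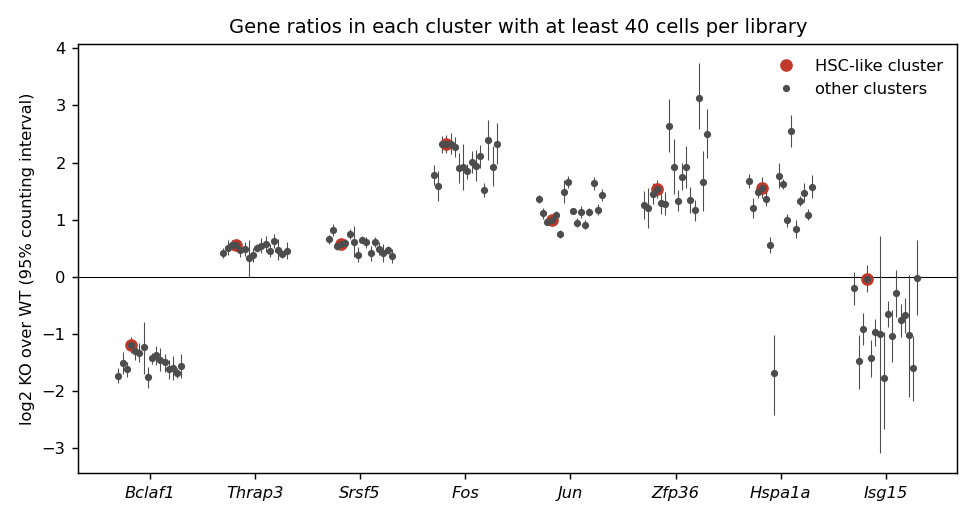
Log2 ratio (KO over WT) of 8 genes in each of the 16 clusters with at least 40 cells per library, with 95% counting intervals and the HSC-like cluster in red. Bclaf1 lies below 0 and Fos, Thrap3 and Srsf5 lie above 0 in all 16 clusters, and the genes were chosen after their values were seen.

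Cell cycle phases were scored with each cell thinned to 13589 UMIs, which left out 679 WT and 122 KO cells. The S phase share was 30.1% (28.8 to 31.4) in WT and 25.7% (24.0 to 27.5) in KO, a difference of -4.34 points (-6.47 to -2.18). The G2 and M phase share was 35.5% (34.2 to 36.9) and 41.4% (39.4 to 43.3), a difference of 5.83 points (3.48 to 8.18). Without thinning the differences were -0.26 and 7.70 points. At 27178 UMIs per cell, which left out 3415 WT and 943 KO cells, the G2 and M phase difference was -6.20 points. HSC-like cells scored as G1 at 85.8% in WT and 88.3% in KO among the 423 and 231 that reached 13589 UMIs, and at 92.8% and 89.2% without thinning. Free RNA also enters these calls, and they are not read as cycling.

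Antibody tags were more numerous per cell in the KO library for each of the 6 antibodies, and CD201 (EPCR, a surface marker of HSCs encoded by Procr) differed most. Its median was 10 tags per cell in WT and 37 in KO, and its centred log ratio was 0.66 higher in KO. The difference was 0.35 in HSC-like and 0.82 in erythroid-like cells, while Procr messenger RNA had 12.5 CPM in WT and 8.58 CPM in KO. In empty droplets CD201 made up 7.69% of tags in WT and 13.3% in KO. Sca1 had median tags of 155 and 175.5 and a centred log ratio difference of -0.48. CD117 (c-Kit) had 694 and 1012 tags (-0.24), CD48 had 2725 and 4516 (-0.098), CD150 had 13 and 25 (0.063) and CD34 had 56 and 101 (0.010). On log counts the CD48, CD117 and Sca1 differences were 0.51, 0.38 and 0.12. Cells with CD150 and without CD48, the usual surface gate for HSCs, made up 11.6% of WT and 10.5% of KO cells, a difference of -1.07 points (-2.48 to 0.41), and 8.19% and 6.37% on log counts, a difference of -1.82 points (-2.98 to -0.61). Of the cells in this gate, 66.7% were HSC-like in WT and 48.6% in KO, and on log counts 74.9% and 70.0%. Cells without CD150 and CD48 differed by 2.04 points (0.51 to 3.63) and cells with both by 1.59 points (0.050 to 3.20), against -4.94 and 10.6 points on log counts.

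Marker lists of other cell types were read over all LSK cells. Erythroid progenitor markers had a median log2 ratio of 0.83, mast cell or basophil markers 0.56 and granulocyte-monocyte progenitor markers 0.26. The summed levels differed less for erythroid markers, at 1337 CPM in WT and 1434 CPM in KO. The sums were 697 and 898 CPM for mast cell or basophil and 1378 and 1613 CPM for granulocyte-monocyte markers. Megakaryocyte progenitor markers had 0.070, lymphoid progenitor markers -0.029 and HSC markers -0.22. Endothelial markers, 4 of 10 of which were measured and which include genes that HSCs express, had -0.23. Medians of few measured markers were 0.17 for hepatoblasts or hepatocytes, 0.014 for stellate or mesenchymal cells, -0.079 for B cells, -0.20 for T, NK or innate lymphoid cells, -0.045 for neutrophils and -0.052 for monocytes, macrophages or dendritic cells. Eosinophil markers were too low for a median, with a summed level of 0.792 CPM in WT and 9.29 CPM in KO.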

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

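The rule that set the interferon result apart was loosened after a stricter form had picked nothing, and the list and classes were compared after their values were seen. The medians of interferon response genes had opposite signs in HSC-like and erythroid-like cells, and the HSC-like median lay near that of all genes in the class (0.095) and within the middle 95% of random lists (-0.012 to 0.17). Their median log2 ratio was 0.11 (0.0038 to 0.17, 32 genes, percentile 70.6 among random lists) in HSC-like cells and -0.27 (-0.38 to -0.11, 15 genes, percentile 0) in erythroid-like cells. The difference was not tested, and a difference in free RNA between the libraries was not told apart from it. In HSC-like cells 20 genes were higher and 12 lower, and in erythroid-like cells 4 were higher and 11 lower. In HSC-like cells 1 KO cell held 29.0% of the Ifit1 UMIs, and with median-of-ratios scaling the median of Interferon response in HSC-like cells was 0.0030. No biological explanation was tested.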

How the results depend on the processing

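The Sca1 split, the CD150 and CD48 gate, the histone list, the minimum of 4000 UMIs, the highest doublet scores, the background of 100 to 300 UMIs and the removal of the 5% of cells highest for immediate early genes were chosen after the data were seen. Under all alternatives, 78 values of the main results moved by less than their counting interval, 30 moved further with the sign kept and 3 reversed; for the other results these counts were 1415, 560 and 27. Under the alternatives run for each, Bclaf1 ran from -1.59 to -1.34, the immediate early median from 0.86 to 1.13 and the erythroid-like difference from 6.51 to 7.62 points, or from 5.76 with the weighting by Sca1 tags given below. The cause was not tested except where stated. No paired analysis was possible because each genotype was 1 library, and for that reason leaving out a replicate was not possible.

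At 2 times the UMI minimum, which removes the shallow cells, the HSC-like difference was 0.29 points, and the interferon, immediate early and heat shock medians were -0.14, 1.00 and 0.13; H2-Eb1 was -0.023. A mitochondrial limit of 5% gave an interferon median of -0.18. With cells thinned to the same UMIs Bclaf1 was -1.44, the interferon, immediate early and heat shock medians were -0.098, 1.08 and 0.11, and the median of MYC targets was -0.038. With WT cluster weights these were -0.071, 0.98, 0.13 and -0.0056, haemoglobins had -0.11, Hba-a1 -0.075 and Bok 0.038. Subtracting a background of 10 to 100 UMIs moved the median of all genes from 0.067 to 0.20, more than any other scaling. It gave -1.34 for Bclaf1, -0.15, 1.13 and 0.31 for the interferon, immediate early and heat shock medians, 0.015 for NRF2 and oxidative stress, -0.34 for G6pdx, -0.20 for mt-Nd3, 0.27 for Msmo1 and -0.65 for Ddx3y. A filter at 50 CPM leaves fewer genes and gave -0.31 for interferon, 0.86 for immediate early genes and -0.48 for haemoglobins.

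Median-of-ratios scaling moved the median of all genes to -0.0017. It gave -1.59 for Bclaf1, 0.88 for immediate early genes, 0.10 for heat shock, and turned the small median of MYC targets (-0.0070) and those of BCL2 family (-0.014) and autophagy and lysosome genes (-0.016). It moved the median of Interferon response in HSC-like cells to 0.0030 and gave there 0.89 for immediate early genes, -0.067 for heat shock, -0.025 for S phase, -0.022 for ribosome biogenesis, -0.057 for mitochondrially encoded genes, -0.031 for glycolysis and -0.012 for autophagy and lysosome genes. In granulocyte-monocyte-like cells mitochondrially encoded genes had -0.075 and autophagy and lysosome genes -0.0026, and in erythroid-like cells S phase genes had -0.0080.

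Resolution 0.5 gave a granulocyte-monocyte-like difference of 3.64 points. Keeping genes that differ over 2-fold gave 3.53 points for that class and -0.067 for the lymphoid-like class. Clusters from WT cells alone gave 0.37 points for granulocyte-monocyte-like and 1.06 for megakaryocyte-like cells. Among cells at or over their library's median share of Sca1 tags the HSC-like difference was -5.76 and the megakaryocyte-like difference 1.16 points. Without thinning the S phase difference was -0.26 points, and at 27178 UMIs per cell the G2 and M phase difference was -6.20 points. On log counts the CD48, CD117 and Sca1 tag differences were 0.51, 0.38 and 0.12, cells without CD150 and CD48 differed by -4.94 points in place of 2.04, and cells with both by 10.6 in place of 1.59 points. Depth limits the levels in HSC-like cells, which rest on 693 WT and 259 KO cells.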

Other observations

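The tests by WT cluster weights and by cluster range on immediate early genes, by Sca1 tags and by S phase genes were chosen after the results, or related ones, had been seen, as were the settings at 4000 UMIs and without the highest 5% of cells. The histone list and the genes of this paragraph were also chosen after their values were seen. Over the 16 clusters with at least 40 cells per library, the log2 ratio of Commd10 ran from 0.89 to 2.54 and that of the nuclear long non-coding RNA Neat1 from 0.41 to 1.24. Presence of Cre and loss of Bclaf1 were not told apart for either gene. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, had a median log2 ratio of 0.31 over all LSK cells (percentile 100), with 51 of 56 higher and 26 at least 25% higher. Hist1h2ap had 1.00, Hist1h2ai 0.81 and Hist1h2br 0.79, and these copies share reads. The median was 0.33 in HSC-like, 0.39 in lymphoid-like, 0.42 in granulocyte-monocyte-like, 0.19 in megakaryocyte-like and 0.30 in erythroid-like cells.

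Eosinophil granule genes were rare in both libraries and more abundant in KO. Prg2, the major basic protein gene, had 48 UMIs in WT and 506 in KO, Prg3 had 53 and 256, and Ear1, an eosinophil ribonuclease gene, had 4 and 125. At least 5 UMIs of these genes were found in 5 WT and 8 KO cells, 11 of them in cluster 14, and 1 KO cell held 33.5% of the KO UMIs.

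Immediate early genes were higher in the KO library, with a median log2 ratio of 0.95. Class make-up and a few strongly induced cells are argued against, as the median was 0.98 at WT cluster weights and 0.93 without the highest 5% of cells. In thinned cells the median was 1.08, but thinning keeps the expected proportions of each cell, so it cannot decide on depth per cell. Free RNA as the whole cause is argued against too: at the depth of empty droplets it could give 1.02% of the KO excess and at the haemoglobin bound 42.4%. The latter counts the free RNA of KO alone and lies between the bounds set for and against free RNA. WT would gain 45.0% of that excess at its own bound, so with both libraries at their bounds free RNA would not raise KO over WT. Both are upper bounds, so a part stays open. Subtracting the 10 to 100 UMI background at the haemoglobin shares gave a median of 1.13. It took the larger share from WT and raised the median of all genes from 0.067 to 0.20, so this rise does not count against free RNA. Handling of the KO pool before capture stays open: the lowest cluster median was 0.75, higher values in every cluster are what handling would give, and with 1 pool per genotype handling and genotype cannot be told apart. A hypothesis left untested here is that loss of Bclaf1 may itself raise these genes.

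The KO library held fewer HSC-like and more erythroid-like cells. Removal of cells between 4000 UMIs and the minimum is argued against, since at 4000 UMIs in both libraries the HSC-like difference was -3.51 points (-4.89 to -2.08), but at 2 times the minimum it was 0.29 points (-0.90 to 1.56), so an effect of depth stays open. When the KO cells were weighted to the WT spread of Sca1 tag shares, in deciles, the erythroid-like difference was 5.76 points (4.66 to 6.82). Erythroid-like cells had Ly6a, which encodes Sca1, at 0.48 CPM in WT and 0.32 CPM in KO, yet median Sca1 tags of 51.5 and 95.5. Sca1 made up 21.6% and 22.7% of tags in empty droplets. Their tags may thus be largely free tags, and this weighting cannot decide on a looser Sca1 gate as the cause of the erythroid-like difference. The HSC-like difference became 1.16 points (-0.013 to 2.49), which is consistent with a looser Sca1 gate in the KO sort, but HSC-like cells had the highest median of Sca1 tags among the named classes in WT (365), so a loss of such cells by genotype may give the same value. A split at each library's median Sca1 share, seen before, had kept both differences (-5.76 and 6.79 points), and a correlation of Sca1 with cluster shares, also seen before, was dropped.

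For the histone genes no tested explanation was settled. The S phase median was 0.32 of the histone median, between the bounds set for a larger share of cells in S phase and against it. With cells thinned to the same UMIs the median was 0.25, over the bound set against a depth effect by less than its counting spread, and at WT cluster weights it was 0.18. Thinning keeps the expected proportions of each cell, and only weights cells equally and leaves out shallow ones, so it cannot decide on depth. Histone genes were not left out of the clustering as a group and were among the top genes of clusters 0 and 4. The cluster weights may thus rest partly on these genes, so they cannot decide on make-up. Make-up may account for part and cannot be told apart from genotype here, and depth stays open. Capture of transcripts without poly(A) tails was not tested.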
